A study of Mus musculus with 5 samples.

How the data were processed

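Single-cell RNA sequencing of whole lung was deposited for 5 libraries of female C57BL/6 mice aged 5 months, each made from 1 to 3 pooled lungs that had been dissociated enzymatically and sorted for live cells. The libraries were prepared with the 10x Genomics 3' chemistry, version 3, which tags the 3' end of polyadenylated RNA and adds a unique molecular identifier (UMI) to each captured molecule. The deposited matrices hold raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger on the mm10 mouse genome, and hold no normalised values. The authors deposited each matrix both with all barcodes and with the barcodes that Cell Ranger kept as cells, whose smallest total was 500 UMIs. The file headers name Cell Ranger 3.1.0 for control replicate 1 and Pt and version 3.0.2 for MAG4, MAG4/Pt and control replicate 2, although the submitters' notes name 3.1.0 for all. The numbers the libraries carry fall into the same 2 series, and this split was treated as a batch, so that each batch held 1 control library. The batch term in the models was fixed from the library numbers before the data were examined, and the versions were read afterwards. The gene list of 31053 features came from the mouse reference alone and holds no MAGE-A4 transgene and no Cre.

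The 5 libraries were grouped by the genotypes in the labels into control (2 libraries), Pt, MAG4 and MAG4/Pt (1 library each). Barcodes with fewer than 300 detected genes or more than 15% mitochondrial UMIs were removed, and doublets were called in each library with scrublet at an expected rate of 6%, as implemented in scanpy 1.11.5 (Python 3.11.15). Counts were scaled to a common total and log-transformed, 2978 variable genes were reduced to 40 principal components, and a graph of 20 neighbours was clustered with the Leiden algorithm at resolution 2. This gave 63 clusters, of which 3 that mixed cell types were clustered again. Each cluster was named by hand from its leading genes, with marker lists fixed before the data were examined, and 14 clusters in which at least 30% of cells had been called doublets were set aside. Plasma cells were taken as cells of their cluster with at least 5% of their UMIs from immunoglobulin genes. The limits of 30% and 5% and the choice of clusters to divide were made after the clusters had been seen. Of 44137 cells past the filters, 40945 were analysed, and 35963 of them fell into 28 named cell classes. The other 11 clusters were left unnamed. The free RNA of each library was read from its barcodes with 1 to 20 UMIs (empty droplets). Its level in cells was estimated from the UMIs of 9 epithelial genes in lymphoid cells.

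Shares of cell classes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the number of cells per class and library, and each share carries an exact (Clopper-Pearson) 95% binomial interval. Gene expression was compared on UMI counts summed per library and cell class (pseudobulk), with TMM normalisation, filterByExpr and the same edgeR quasi-likelihood test, Benjamini-Hochberg adjustment over genes within a class and contrast, and a threshold of 0.05. The 6 contrasts were each genotype against control, MAG4/Pt against Pt and against MAG4, and the interaction, which is the difference of MAG4/Pt from MAG4 minus that of Pt from control. The 13 classes with at least 20 cells in each library were tested. A further 6 classes with 10 to 19 cells in their smallest library, among them alveolar and interstitial macrophages, were added after the data had been seen and are reported apart. The model had 1 residual degree of freedom, which came from the difference between the control libraries. The p-values of this model therefore rest on the spread between the 2 control libraries, which lay in different batches. Each other genotype is 1 library that was assumed to vary in the same way. The spread was pooled over genes. In T, gamma-delta T, B and NK cells, aerocytes, non-classical monocytes, cDC2 and neutrophils the prior degrees of freedom were infinite. They were infinite too in the added alveolar and interstitial macrophages, cDC1, and pericytes with smooth muscle. A gene's own spread had no weight in these classes. An exact permutation of 1 library against 2 could not serve as a test at this threshold. Expression is given as CPM, the UMIs of a gene scaled to a fixed total of the class in a library, fold changes as log2 values with a standard error (SE) from the fit, and SE is the error wherever a value follows the sign ±.

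The 21 gene lists were fixed before the data were examined. Each was tested in its listed classes with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 and again with an estimated correlation. Benjamini-Hochberg adjustment covered 318 tests of 53 list and class pairs. At the preset correlation camera compares genes with one another, so its p-values do not measure spread between libraries. With an estimated correlation camera had 1 residual degree of freedom, and its lowest adjusted p was 0.654 for every list. That setting could hardly pass a list, so its outcome is no evidence against one. Tests in the added classes were adjusted apart. Members past the gene test were counted once adjusted over all genes of the class and once adjusted over the list alone. The lists of surfactant and AT2 genes, club cell secretory genes and transitional epithelial genes were fixed for alveolar type 2 (AT2) and club cells and were not tested, because the smallest library held 6 AT2 cells and 1 club cell.

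Named genes followed a rule fixed before the data were examined. In each comparison with control the 5 classes with most calls were taken, and in each of them the 3 genes with the largest log2 fold change per direction among calls that differed at least 2-fold in the same direction from each control library, with at least 50 CPM in the higher genotype. For the contrasts of MAG4/Pt with Pt and with MAG4 the top 2 per direction were taken. Mitochondrial, ribosomal protein, haemoglobin and predicted genes, variable segments of antigen receptors, and markers of other classes were left out. Scgb1a1 and mouse Magea genes in epithelial cells, list members past the test, Cxcl12 in endothelial and stromal cells and immunoglobulin constant genes in B cells were always reported. Other genes named in the text were chosen after their values were seen, and the text says so where they appear.

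On simulated data in which 200 genes of general capillary cells were raised or lowered in MAG4/Pt, the test recovered 100% of 4-fold and 41% of 2-fold changes, with 10 false calls among 151. In T cells it recovered 92% and 9%, with 4 false calls among 105. The share test recovered 66.7% of simulated 4-fold rises with 0.26 false calls per simulation. These rates hold only for the spread between libraries set in the simulation. The spread fitted to the real shares was 0.685 (common coefficient of variation). How often the test misses a 4-fold rise in these data was therefore not shown. Intervals and limits on counts cover counting error only.

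Alternatives fixed beforehand were size factors by relative log expression, DESeq2 1.42.0, no filter on low counts, an additive model of the Pt and MAG4 genotypes, the same with a batch term, each control library left out, a stricter cell filter of at least 500 genes and at most 10% mitochondrial UMIs, doublets kept, naming of cells by marker score, subtraction of free RNA, and counts thinned to the smallest total. With a control library left out, 4 libraries of 4 genotypes remained, so the additive model supplied the residual degree of freedom. In an additive model MAG4 against control and MAG4/Pt against Pt are 1 coefficient, as are Pt against control and MAG4/Pt against MAG4, so the counts of each pair are 1 fit. The share of plasma cells was also fixed beforehand to be counted as B-lineage cells with at least 3 of 8 plasma cell markers. Chosen after the data had been seen were the added classes, the ratios within a batch, the counts without genes held by 1 cell or called in at least 4 classes, the test of neighbouring genes, and the settings applied to list genes in T cells and alveolar macrophages. Gene positions are those of GENCODE M21 on GRCm38, and matplotlib 3.10.9 drew the figures.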

Results

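Whole lungs were profiled cell by cell to ask how lung tissue differs between mouse genotypes, some of which carry the human cancer-testis antigen MAGE-A4 as a transgene switched on by a Cre recombinase active in club cells. The 5 libraries came from 4 genotypes. Control mice, labelled Cre-MAG4/Pt, had no Cre and kept the MAGE-A4 transgene silent (2 libraries). Their label thus names Pt as well as the transgene. The other genotypes had Cre and are named as labelled, Pt without the transgene, MAG4 with it, and MAG4/Pt with it on the Pt genotype (1 library each). The deposited cell barcodes numbered 9460 in control replicate 1, 8543 in control replicate 2, 7638 in Pt, 8489 in MAG4 and 11895 in MAG4/Pt. Their total UMIs were 46867071, 51786649, 46550183, 46539297 and 74690435 in the same order, and the median barcode held 4178, 4971, 4779.5, 4626 and 4912 UMIs. After filtering, 8625, 7495, 6898, 7515 and 10412 cells were analysed. Control replicate 1 and Pt form 1 batch, and control replicate 2, MAG4 and MAG4/Pt form the other, so each genotype had 1 control library in its own batch. The p-values of the main gene and share tests rest on the spread between the 2 control libraries, which lay in different batches. For genes this spread was pooled over the genes of a class. With a control left out no control pair remained, and the additive model supplied the error. No genotype other than control was replicated.

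Club cells, in which the Cre is active, numbered 1 and 3 in control replicates 1 and 2, 5 in Pt, 3 in MAG4 and 10 in MAG4/Pt. The 8 mouse Magea genes had 0 UMIs in epithelial cells, and the human transgene is not in the reference, so MAGE-A4 expression was not measured. Scgb1a1, the secretoglobin that marks club cells, reached 333812 CPM in club cells of control replicate 1, 320225 in control replicate 2, 307676 in Pt, 278149 in MAG4 and 244941 in MAG4/Pt. Outside club cells Scgb1a1, counted there after its values were seen, was called higher in 10 of 13 classes of Pt, with a median log2 fold change of 2.61, and in 8 with a median of 2.31 after subtraction of free RNA. In MAG4/Pt it was called higher in 3 classes against control (median 1.07) and in 5 against MAG4 (median 1.95). In MAG4 against control it was called higher in 0. Scgb3a2, another club cell gene, was called higher in 6 of 10 classes of Pt and in 3 of MAG4/Pt against control. The estimated free RNA was 6.62% of UMIs in Pt against 1.84% and 1.00% in the controls, and its subtraction left most of the rise. The estimate itself rests on epithelial UMIs in lymphoid cells, so this subtraction cannot decide the source. Scgb3a2 UMIs were 20.58% of Scgb1a1 UMIs in the 13 classes of Pt and 17.38% in its empty droplets. In MAG4/Pt they were 19.09% and 17.94%, and in MAG4 10.31% and 13.17%. In control replicates 1 and 2 they were 1.89% and 3.27% in the classes, against 8.30% and 8.47%. The source of these UMIs stays open.

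Lymphocytes, endothelial cells and monocytes made up most cells of every library. B cells were 24.6% of cells in control replicate 1 and 9.78% in control replicate 2, against 15.2% in Pt, 9.23% in MAG4 and 9.76% in MAG4/Pt. T cells were 14.9% and 17.7% in the controls, 8.70% in Pt, 20.8% in MAG4 and 19.8% in MAG4/Pt. Non-classical monocytes, which patrol the vessel wall, were 4.21% and 4.35% in the controls and 9.44% in Pt, a log2 difference of 1.14. Plasma cells numbered 10 and 3 in the controls, 11 in Pt, 2 in MAG4 and 26 in MAG4/Pt, and neutrophils were 3.67% of MAG4/Pt cells against 1.28% of MAG4 cells (log2 1.52 ± 0.34). None of the 28 classes passed edgeR's test in any of the 6 contrasts, with lowest adjusted p = 0.694 for Pt against control, 0.813 for MAG4 against control, 0.702 for MAG4/Pt against control, 0.669 for MAG4/Pt against Pt, 0.633 for MAG4/Pt against MAG4 and 0.827 for the interaction. At unadjusted p < 0.05 edgeR counted 1, 0, 0, 2, 1 and 0 classes in that order, and DESeq2 passed 0 classes with 2, 1, 1, 4, 0 and 0 below the unadjusted limit. Without control replicate 2, erythroid cells alone passed, in MAG4 and MAG4/Pt against control and in MAG4/Pt against Pt (adjusted p = 0.00227 for MAG4). They were 1.79% of cells in control replicate 1 and 1.36% in Pt, and 0 cells were found in the other batch.

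**Figure D1:**
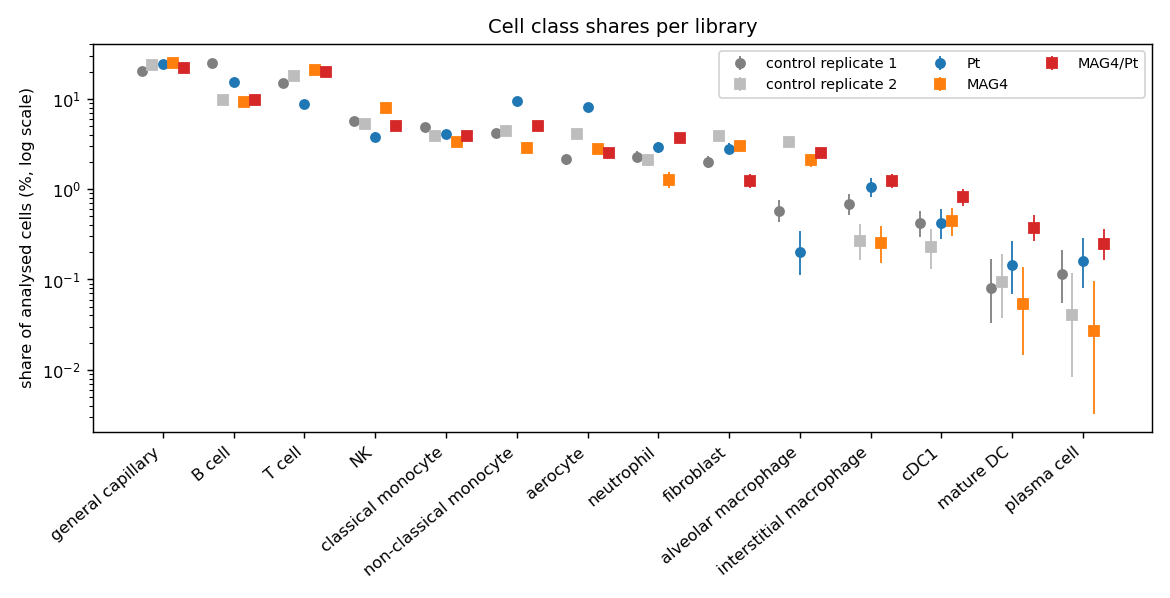
Share of analysed cells (percent, log axis) in 14 of the named cell classes, 1 point per library, with exact 95% binomial intervals. The control libraries lie far apart for B cells, at 24.6% and 9.78%, and close together for non-classical monocytes, at 4.21% and 4.35%, where Pt lies at 9.44%.

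Pt was compared with control to ask how the cells around the club cells differ without MAGE-A4. Control mice lack Cre and carry the silent transgene, so Cre and the missing transgene cannot be told apart from the Pt genotype here. T cells of Pt expressed more of the genes of regulatory and activated T cells. The costimulatory receptor Tnfrsf4 was 2.67 ± 0.41 log2 units higher (adjusted p = 3.6e-08) and the regulatory T cell transcription factor Ikzf2 2.00 ± 0.39 (0.00012). The inhibitory receptor Lag3 was higher by 3.40 ± 0.50 (1.3e-08), Tnfrsf9 by 3.15 ± 0.52, Pdcd1 by 2.49 ± 0.49, the lineage factor Foxp3 by 2.26 ± 0.43 (6.2e-05) and Ctla4 by 1.60 ± 0.39. Of the 19 measured genes of the fixed list of exhaustion and regulatory genes, 9 were called higher over all genes and 15 adjusted over the list alone, with a median log2 fold change of 1.87 (camera adjusted p = 1.6e-42, and adjusted p = 0.654 with an estimated correlation). The T cell cluster led by Ctla4 and Foxp3 held 178 of the 600 T cells of Pt, against 121 and 147 cells of the controls, whose T cells numbered 1287 and 1325, so the rise coincided with a larger part of such cells. Within the batch Tnfrsf4 was 2.60 and Ikzf2 2.35 log2 units above control replicate 1. The 9 calls became 0 without control replicate 1 and 12 without control replicate 2. Of the 17 cytotoxicity genes, Gzmk, higher by 2.00 ± 0.42, and the chemokine Xcl1, higher by 2.36 ± 0.44, were called over all genes, and 5 adjusted over the list alone (median 0.80, camera 5.9e-11, adjusted p = 0.654 with an estimated correlation). The T cell cluster led by Gzmk and Ccl5 held 80 of these 600 T cells of Pt, against 93 of 1287 and 77 of 1325 in the controls, so this rise too coincided with a larger part of such cells.

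**Figure D2:**
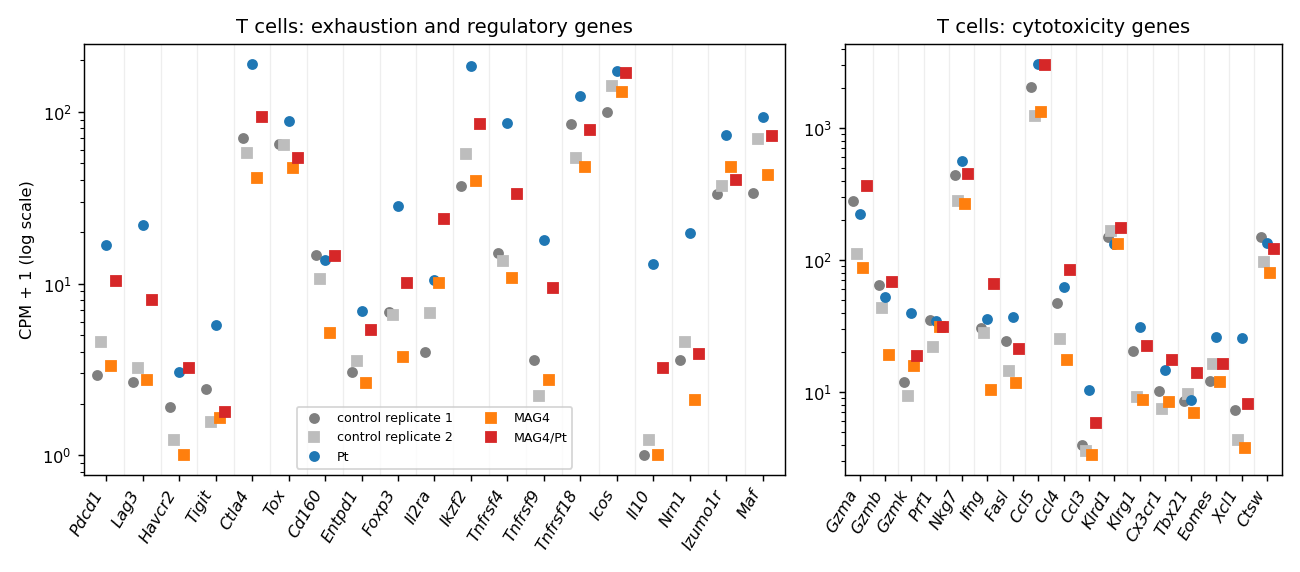
Expression in T cells (CPM plus 1, log axis) of the exhaustion and regulatory list and the cytotoxicity list, 1 point per library. Of the exhaustion and regulatory genes, 9 were called higher in Pt and 3 in MAG4/Pt than in control.

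In general capillary cells of Pt, Cd74, the invariant chain of MHC class II, was higher by 1.35 ± 0.23 log2 units (adjusted p = 0.00036) and H2-DMa, which loads peptide on class II, by 1.10 ± 0.26 (0.026), with 7 of 9 class II genes adjusted over the list alone (median 0.93, camera 1.8e-22, adjusted p = 0.654 with an estimated correlation). The lymphocyte-attracting chemokine Cxcl9 was higher by 2.54 ± 0.51 (0.0053) and the adhesion molecule Vcam1 by 1.47 ± 0.31 (0.0068). The capillary cluster led by Cxcl9 and interferon-induced genes held 127 of the 1694 general capillary cells of Pt, against 65 of 1753 and 62 of 1790 in the controls. Cxcl10 rose by 1.74 ± 0.34 with 54.2% of its UMIs in 1 cell. The matricellular gene Sparcl1 (chromosome 5, 104079111 to 104113733) was 1.80 ± 0.27 higher (7.6e-05), at 672 CPM against 240 and 147 in the controls, and the transcription factor Hlx 1.54 ± 0.27. The FOXO target Klf2 was higher by 1.43 ± 0.25 (0.00057), while the FOXO list as a whole had a median of -0.33 (camera adjusted p = 0.029, and adjusted p = 0.706 with an estimated correlation). Interferon-stimulated genes had a median of 0.29 in these cells (camera 1.2e-05, adjusted p = 0.709 with an estimated correlation) and Zbp1, a sensor induced by interferon, was called (1.15 ± 0.28). In aerocytes, the capillary cells of gas exchange, Mettl24 rose by 3.11 ± 0.33, Gchfr by 2.15 ± 0.29 and Sparcl1 by 1.80 ± 0.32, while the xenobiotic enzyme gene Cyp1a1 fell by 3.49 ± 0.36 (within the batch it fell by 2.88).

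Non-classical monocytes held the most calls, 138, followed by T cells with 107, general capillary cells with 80, aerocytes with 68 and NK cells with 57. In these monocytes the uridine phosphorylase Upp1 (chromosome 11, 9118103 to 9136170) rose by 5.83 ± 0.58 log2 units (adjusted p = 4.9e-20), Wnt6 by 3.40 ± 0.44 and the formyl peptide receptor Fpr1 by 3.28 ± 0.41, with 5.88, 3.45 and 2.85 against control replicate 1 alone. NK cells had more of the inhibitory receptor gene Klra5, by 3.34 ± 0.41, of Spp1, by 2.83 ± 0.38, and of Slamf1, by 2.68 ± 0.43. Klri2 fell by 6.65 ± 0.61. Klra5 and Klri2 belong to multigene families, and whether their tags were shared with related genes was not tested, so both values are uncertain. Across the 13 classes 674 calls were made, 320 higher and 354 lower, of 4619 at unadjusted p < 0.05. This split depended on the setting, with 305 higher and 645 lower after subtraction of free RNA, 236 and 42 in the additive model with a batch term, and 204 and 35 without control replicate 2. In 37 of the calls more than 50% of the UMIs lay in 1 cell. Without control replicate 1 the count was 428 and without control replicate 2 it was 239, of which 108 and 110 were among the 674. Of the 30 genes named by the fixed rule, 7 and 12 stayed past the threshold.

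A set of 21 genes was lower in at least 4 classes of Pt, and 12 genes were higher in as many. Trim12a, of an antiviral gene family on chromosome 7 (104299894 to 104315466), was lower in 12 of 12 classes, with a mean of 1.84 CPM in Pt against 92.0 and 44.3 in the controls. In T cells it fell by 5.32 ± 0.62 log2 units (adjusted p = 8e-14), and in NK cells the control to Pt ratio was 76.4 (counting interval 21 to 633). The next 6 genes named, and Gm26740, were chosen from the 21 after their values were seen. The neighbours Trim30d, Trim5 and Trim34a were lower in 8 of 10, 7 of 9 and 6 of 11 classes, and Gvin1, also on chromosome 7, in 6 of 8. On chromosome 1 the interferon-inducible Ifi206 (173468485 to 173491041) and Ifi213 (173566283 to 173599274) were lower in 8 of 11 and 8 of 8. Ifi213 stood at 0.279 CPM in Pt, at 33.8 and 27.4 in the controls, 42.2 in MAG4 and 36.7 in MAG4/Pt. Gdpd3 was lower in 10 of 13 classes, and in non-classical monocytes it fell by 5.19 ± 0.48 (within the batch it fell by 3.24). Calls in the 21 lower and 12 higher genes made up 208 of the 674. Against control replicate 1 alone, by mean CPM over classes with 1 CPM added, the 21 genes had a median of -2.06, from -5.03 to 0.35. BC018473 and Gm26740 were as low in control replicate 1 as in Pt, so these 2 followed the batch. Trim12a and its copies share sequence, so the split between them is uncertain. The heat shock genes Hspa1a and Hspa1b, lower in 9 and 11 of 13 classes, respond to dissociation.

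**Figure D3:**
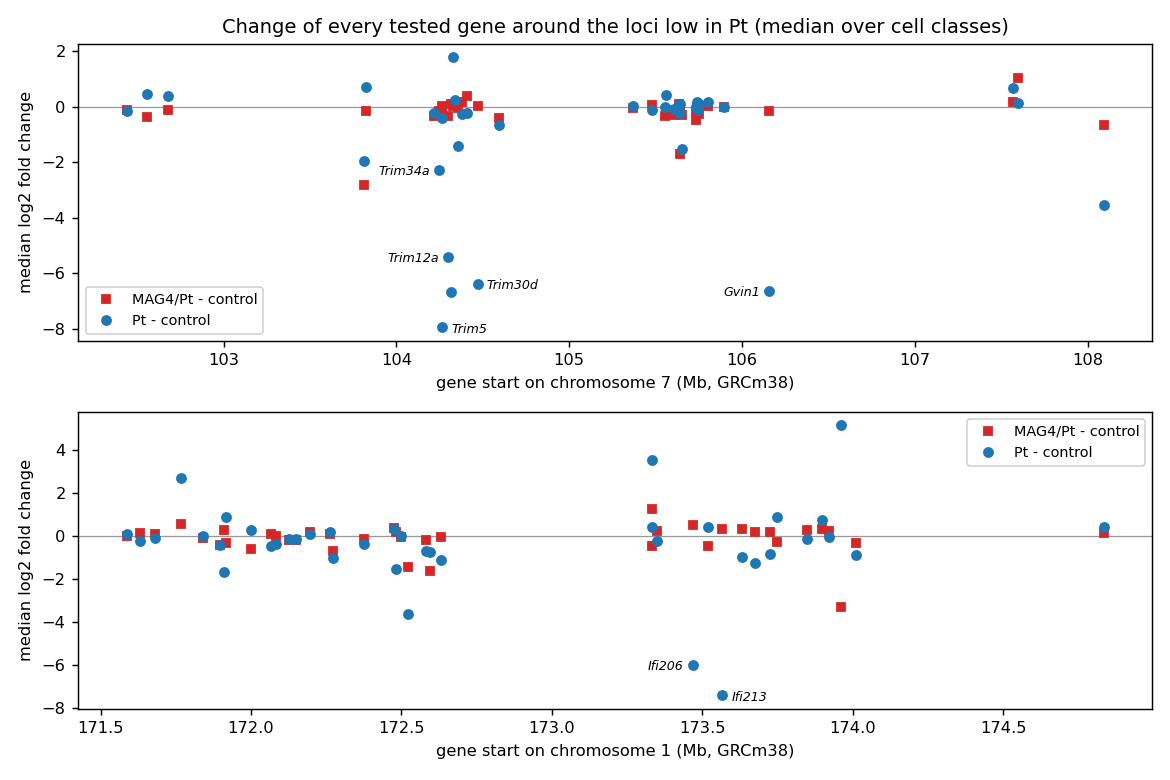
Median log2 fold change over cell classes, Pt and MAG4/Pt against control, of every tested gene around loci on chromosomes 7 and 1, by gene start (Mb, GRCm38). The named genes were called lower in at least 4 classes of Pt, Trim12a in 12 of 12, and their MAG4/Pt values lie near 0.

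MAG4 was compared with control to ask how the lung differs when the MAGE-A4 transgene is switched on. Control mice also lack Cre, and their label names Pt, which the label of MAG4 does not. The active transgene, Cre and the missing Pt part therefore cannot be told apart here. In fibroblasts the glycogen-binding gene Stbd1 was higher by 2.03 ± 0.40 log2 units (adjusted p = 0.00079) and Pdxdc1 by 1.69 ± 0.45 (0.049), and the chemokine Cxcl10 fell by 5.39 ± 0.64 (9.2e-12), and within the batch it fell by 3.83. Non-classical monocytes had more of the inhibitory Fc receptor Fcgr2b, by 2.23 ± 0.39 (5e-05), and of the matrix protein gene Thbs1, by 1.92 ± 0.41 (0.0031), while the chemokine Ccl4 fell by 1.61 ± 0.40 (0.027) and Ccl3 fell by 1.48 ± 0.38 (0.039). NK cells had more of the chaperone Hsph1, by 1.83 ± 0.36, and of the hydroxylase P4ha1, by 1.59 ± 0.38. Neutrophils had Gzmb at least 26.2-fold higher, from 3 of 96 cells with 84.6% of its UMIs in 1, and Ccl5 higher by 4.83 ± 0.52 with 61% of its UMIs in 1 cell. In cDC2 the calls in Lyz1 and Retnla had 98.2% and 86.3% of their UMIs in 1 cell, and Cxcl2 fell by 3.99 ± 0.61 (1.2e-07). The cDC2 cluster led by Mgl2 and Ccl17, with Retnla among its leading genes, held 32 of 40 cDC2 of MAG4, against 12 of 60 and 27 of 47 in the controls. Ccl5 in fibroblasts fell by 3.32 ± 0.51, with 98% of its UMIs in 1 cell, and the change was 0.86 without control replicate 1.

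Calls against control numbered 181 in MAG4, 75 higher and 106 lower, of 3256 at unadjusted p < 0.05. The split turned to 3131 higher and 1512 lower without control replicate 2 and to 12 and 5 in the additive model. Fibroblasts held 34, non-classical monocytes 22, neutrophils 21, and NK cells and cDC2 20 each. Without control replicate 1 the count was 82, with 15 of the 181 kept, and without control replicate 2 it was 4643, with 59 kept, because MAGE-A4 and batch then coincide. Of the 25 named genes 4 stayed past the threshold without control replicate 1, and of the 24 with a value 11 without control replicate 2. Among the lists, interferon-stimulated genes had a median of 0.95 in neutrophils (camera 1e-15) and 0.40 in classical monocytes (1.6e-09), with 0 members called. T cell cytotoxicity genes had a median of -0.45 (1.7e-08), with 0 called and 3 lower adjusted over the list alone, and class II genes in capillary cells had a median of -0.51 (8.2e-08). Each of these had adjusted p = 0.654 with an estimated correlation.

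MAG4/Pt was compared with control to ask how the lung differs when the genotypes of Pt and MAG4 are combined. Control mice lack Cre, so an effect of Cre itself cannot be told apart here either. In aerocytes the neurotrophin receptor Ntrk2 (chromosome 13, 58806569 to 59133970) was higher by 3.68 ± 0.45 log2 units (adjusted p = 8.9e-13), the hypoxia-induced Ankrd37 by 2.36 ± 0.37 (2.8e-07) and Sparcl1 by 2.31 ± 0.32 (1.7e-09), and against control replicate 2 alone by 3.66, 2.57 and 2.18. In general capillary cells, where Ntrk2 and Sparcl1 were chosen after their values were seen, Ntrk2 was higher by 2.25 ± 0.26 (1.1e-06), Ankrd37 by 2.57 ± 0.28 (3.4e-07), the mitophagy gene Bnip3 by 1.43 ± 0.29 (0.015), Sparcl1 by 1.59 ± 0.27 and the angiogenic glycoprotein Lrg1 by 1.39 ± 0.27. Of the general capillary clusters, the one led by Ntrk2, Cxcl12 and Sema3c held 1056 cells in MAG4/Pt against 302 and 346 in the controls, 364 in Pt and 297 in MAG4. The list of glycolysis and hypoxia genes had a median of 0.25 (camera 5.9e-10, adjusted p = 0.654 with an estimated correlation), with 2 members called and 2 adjusted over the list alone. In large-vessel endothelial cells Esm1, a gene of angiogenic tip cells, fell by 2.32 ± 0.38 (0.0016). The large-vessel cluster led by Esm1 held 65 of 302 such cells in MAG4/Pt, against 56 of 173 and 72 of 204 in the controls. The chemokine Cxcl12 (chromosome 6, 117168535 to 117181367), which retains plasma cells, was called in no endothelial or stromal class against control. In general capillary cells it stood at 651 and 915 CPM in the controls, 627 in Pt, 870 in MAG4 and 1159 in MAG4/Pt, a log2 difference of 0.57 ± 0.26 for MAG4/Pt.

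**Figure D4:**
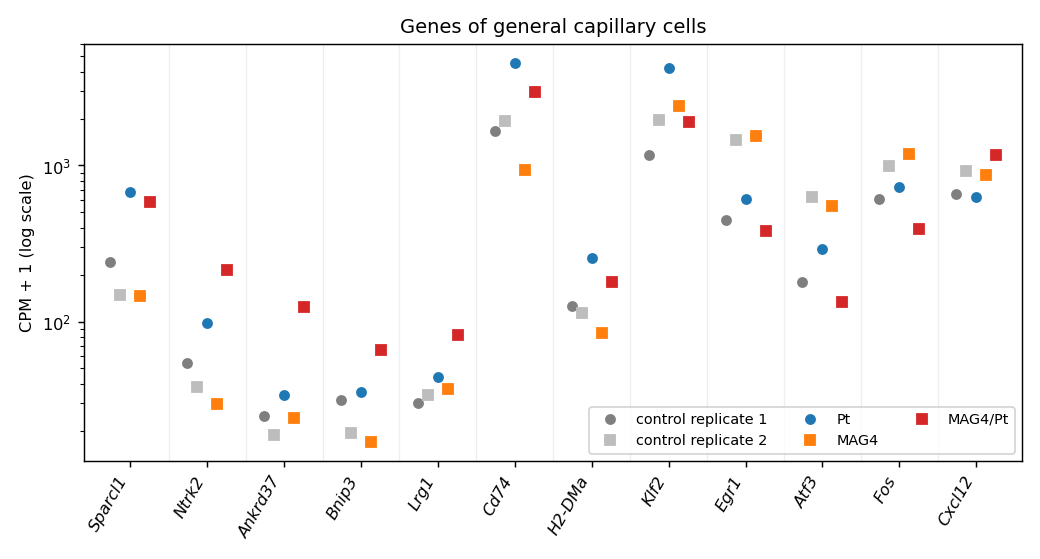
Expression (CPM plus 1, log axis) of 12 genes in general capillary cells, 1 point per library. Sparcl1 lies at 672 CPM in Pt and 583 in MAG4/Pt against 240 and 147 in the controls.

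In B cells of MAG4/Pt 4 of 24 immunoglobulin secretion and plasma cell genes were called higher and 6 adjusted over the list alone (median 0.37, camera 2.8e-13, adjusted p = 0.654 with an estimated correlation). Jchain, which joins secreted antibodies, was higher by 4.16 ± 0.51 log2 units (adjusted p = 7.3e-13), and by 2.12 ± 0.56 in Pt and 2.53 ± 0.57 in MAG4. The gut-homing receptor Ccr9 was higher by 3.97 ± 0.89 (0.0031) and Il10 by 4.20 ± 1.03 (0.012). Ighg2b rose by 4.82 ± 0.42, with 87.9% of its UMIs in 1 of 25 cells. The calcium-binding S100a6 was higher by 2.78 ± 0.36 (4.7e-11), at 514 CPM against 40.8 and 110. The B cell cluster led by Cxcr5 and Fcmr held 686 of 1016 B cells in MAG4/Pt and 411 of 694 in MAG4. In control replicates 1 and 2 it held 198 of 2121 and 468 of 733, so the make-up of the class differed most from control replicate 1. Ighm, Ighd, Igkc and Igha were not called. Immunoglobulin genes made up 0.428% of the UMIs of empty droplets in MAG4/Pt, 0.416% and 0.160% in control replicates 1 and 2, and 0.200% in MAG4, so free RNA differed too, and after its subtraction the list gave camera 1.9e-11. Neutrophils had more Ccl5, by 4.00 ± 0.51 in 48 of 382 cells, and Rgs1, by 3.88 ± 0.54, and the cytokine Il1a by 2.41 ± 0.52 (0.0014), which in MAG4 was higher by 2.73 ± 0.57. In classical monocytes the acute-phase gene Saa3 was higher by 4.39 ± 0.41 (0.00019), and by 3.17 ± 0.43 in Pt. In fibroblasts the neutrophil chemokine Cxcl1 was higher by 2.13 ± 0.42 (0.00081). In cDC2, Il9 and Il17f were at least 169-fold and 28.4-fold higher, all from 1 of 84 cells. T cells had more Il2ra, by 2.36 ± 0.42, and Tnfrsf9, by 2.15 ± 0.51, with 3 regulatory genes called and 6 adjusted over the list alone. Calls numbered 244, 193 higher and 51 lower, of 2964 at unadjusted p < 0.05, led by B cells with 52 and neutrophils with 32. Without control replicate 1 the count was 98, with 41 kept, and without control replicate 2 it was 892, with 115 kept. Of the 21 named genes 6 and 13 stayed past the threshold.

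Alveolar macrophages, which clear surfactant, were added after the data had been seen, since Pt held 14 of them against 50 and 249 in the controls, 157 in MAG4 and 261 in MAG4/Pt. Genes of cholesterol synthesis were higher in both Pt and MAG4/Pt. Fdps was higher by 2.04 ± 0.36 log2 units in Pt (adjusted p = 3.9e-06) and 1.94 ± 0.31 in MAG4/Pt (1e-07), Cyp51 by 1.80 ± 0.37 and 2.04 ± 0.31, and Sqle by 1.98 ± 0.38 and 1.69 ± 0.28. Of 22 measured SREBP genes, 10 were called in Pt and 13 adjusted over the list alone (median 1.25, camera 1.6e-26), 14 and 17 in MAG4/Pt (median 1.16, 8.9e-30), and 0 in MAG4 (median -0.15, 0.59). Both list calls had adjusted p = 0.654 with an estimated correlation. Within batches the medians were 1.25 for Pt over control replicate 1, 1.01 for MAG4/Pt over control replicate 2 and -0.13 for MAG4 over control replicate 2. DESeq2 called 1 SREBP gene in Pt and 0 in MAG4/Pt. The macrophage elastase Mmp12 rose by 4.09 ± 0.43 in Pt and 3.89 ± 0.33 in MAG4/Pt, and Spp1 by 3.77 ± 0.29 and 1.95 ± 0.28. Markers of alveolar macrophages went both ways. Of 2 chosen after their values were seen, Ctsk was higher by 2.40 ± 0.30 and 1.38 ± 0.29, and Ear1 fell by 1.23 ± 0.34 in Pt and fell by 2.23 ± 0.34 in MAG4/Pt. Of 18 inflammatory genes all 18 were called in MAG4/Pt, among them Il1b by 3.23 ± 0.30 and Il6 by 2.15 ± 0.29, and 9 in MAG4. The controls differed from each other in this list by a median of -2.11, and the count in MAG4/Pt ranged from 8 to 16 with 1 control left out.

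**Figure D5:**
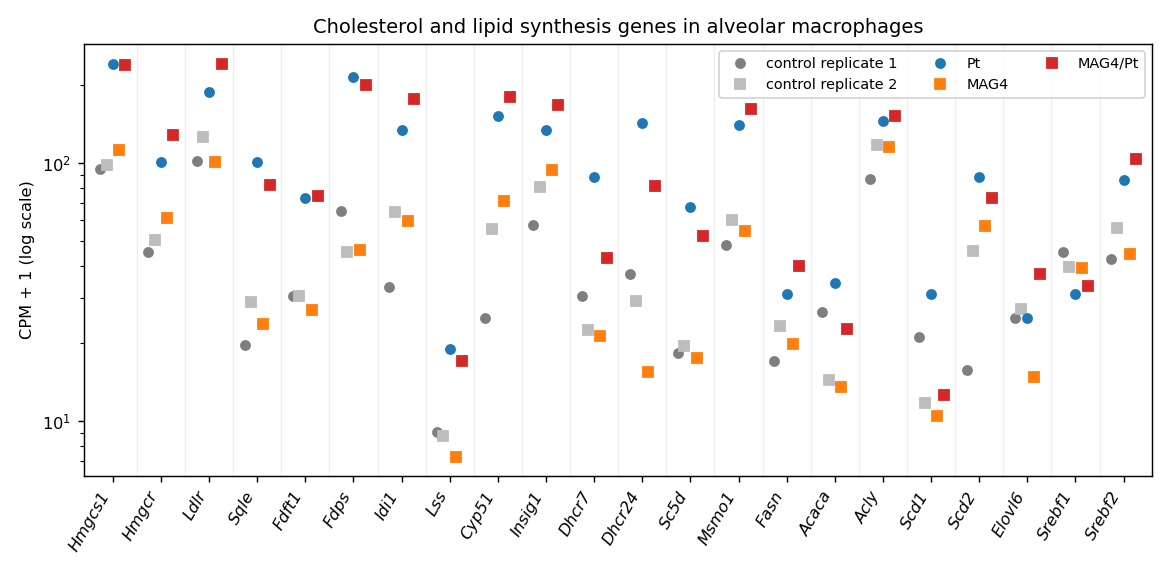
Expression of SREBP genes in alveolar macrophages (CPM plus 1, log axis), 1 point per library. Of the 22 genes, 10 were called higher in Pt and 14 in MAG4/Pt, and 0 in MAG4.

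Interstitial macrophages, added in the same way, expressed more of the B cell chemokine Cxcl13 in Pt, by 2.45 ± 0.41 log2 units (adjusted p = 4.6e-06), and in MAG4/Pt, by 2.34 ± 0.41 (4.8e-06), at 498 and 460 CPM against 159 and 7.87 in the controls and 15.1 in MAG4. In MAG4/Pt 74.5% of its UMIs lay in 1 of 129 cells, and in Pt 52.8% in 1 cell.

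MAG4/Pt was compared with MAG4, in the same batch, to ask what the Pt genotype adds in mice with the transgene. T cells had more interferon gamma (Ifng), by 2.79 ± 0.51 log2 units (adjusted p = 9e-05), the granzymes Gzma, by 2.08 ± 0.45 (0.0021), and Gzmb, by 1.90 ± 0.49 (0.044), and the chemokine Ccl4, by 2.33 ± 0.50 (0.0018). Of 17 cytotoxicity genes 4 were called and 8 adjusted over the list alone (median 1.11, camera 1.8e-33, adjusted p = 0.654 with an estimated correlation), and the 4 became 0 and 2 with 1 control left out. The T cell cluster led by Gzmk and Ccl5, with Ifng among its leading genes, held 255 of 2065 T cells in MAG4/Pt against 70 of 1562 in MAG4. Capillary cells had more Ntrk2, by 2.90 ± 0.34 (3.4e-06), Ankrd37, by 2.39 ± 0.34, Bnip3, by 2.03 ± 0.36, and Cd74, by 1.66 ± 0.28 (0.0027), while the immediate-early gene Egr1 fell by 2.03 ± 0.41 and Atf3 fell by 2.05 ± 0.44, both of which dissociation also induces. The capillary cluster with Ier3 and Hbegf among its leading genes held 345 of 2277 general capillary cells in MAG4/Pt and 1021 of 1862 in MAG4, and 185 of 1753 and 940 of 1790 in the controls, so these falls coincided with fewer such cells. In alveolar macrophages 11 SREBP genes were called and 17 adjusted over the list alone (median 1.26). Fibroblasts had more Cxcl10, by 5.48 ± 0.67 with 44.1% in 1 cell, and B cells more Anxa2, by 3.62 ± 0.57. Calls numbered 234, 176 higher and 58 lower, of 2967 at unadjusted p < 0.05, and 428 (168 higher and 260 lower) and 239 without control replicates 1 and 2, of which 64 and 49 were kept. With a control left out the fit is additive, so these 2 counts are those of Pt against control and no separate check. Of the 15 named genes 10 and 4 stayed past the threshold.

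MAG4/Pt was compared with Pt to ask what the transgene adds on the Pt genotype, across batches. BC018473, which followed the batch, was at least 115-fold higher in non-classical monocytes and at least 102-fold in T cells, and stood at a mean of 0.564 CPM in control replicate 1 and 0.989 in Pt against 82.6, 177 and 243 in control replicate 2, MAG4 and MAG4/Pt. In non-classical monocytes Fpr1 fell by 3.85 ± 0.53 log2 units (adjusted p = 2.6e-10) and Hebp1 fell by 3.73 ± 0.49 (2.8e-11). In general capillary cells Cxcl9 fell by 3.30 ± 0.67 (0.0089), Cxcl10 fell by 1.93 ± 0.42 (0.015) and Vcam1 fell by 1.76 ± 0.37 (0.011). Gdpd3 was higher in T cells by 5.50 and in B cells by 5.41 ± 0.61, the reverse of its fall in Pt. It stood at 13.1 and 166 CPM in T cells and 11.1 and 104 in B cells of control replicates 1 and 2, so part of this difference lies between batches. So does part of the fall of Hebp1, which stood at 37.0 and 8.53 CPM in non-classical monocytes of control replicates 1 and 2. Calls numbered 705, 499 higher and 206 lower, of 5642 at unadjusted p < 0.05, of which 217 lay in genes called in at least 4 classes. In the additive model with a batch term 13 were higher and 26 lower. Without control replicate 1 the count was 82 and without control replicate 2 it was 4643, the same fit as for MAG4 against control and no separate check, and 3 and 17 of the 20 named genes stayed past the threshold.

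The interaction asks whether Pt differs from control as MAG4/Pt differs from MAG4, although only the former pair also differs by Cre. It crosses batches and gave 290 calls, 200 higher and 90 lower, of 3186 at unadjusted p < 0.05. Of the 290 calls, 86 lay in genes called in at least 4 classes. In neutrophils Spp1 was above the sum of the separate effects by 5.07 ± 1.00 log2 units (adjusted p = 0.00037). The interaction was -3.99 ± 0.49 for Esm1 in large-vessel endothelial cells (2.2e-05), -1.77 ± 0.39 for Klf2 in capillary cells (0.03) and -1.84 ± 0.42 for Fosb (0.045). In alveolar macrophages it was -2.44 ± 0.45 for Spp1 and 2.00 ± 0.50 for Il1b.

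Of the 318 planned list tests, those that passed numbered 28 for Pt against control, 26 for MAG4, 29 for MAG4/Pt, 33 for MAG4/Pt against Pt, 30 for MAG4/Pt against MAG4 and 28 for the interaction, and 0 passed with an estimated correlation. That 0 could hardly have been otherwise with 1 residual degree of freedom, so it does not count against the lists. The lists were tested in different numbers of classes, so each count is given with its total. By list, 59 of 78 tests passed for dissociation stress and heat shock, 20 of 30 for interferon-stimulated genes and 14 of 24 for inflammatory cytokines. Plasma cell attraction passed 9 of 30, cytotoxicity 9 of 12 and endothelial activation 9 of 18. MHC class II and haemoglobin passed 7 of 18 each, MHC class I 6 of 12, and T cell exhaustion and regulation 6 of 6. FOXO targets passed 5 of 12 and extracellular matrix 5 of 6. Glycolysis and hypoxia passed 4 of 12, immunoglobulin secretion 4 of 6 and suppressive macrophage genes 4 of 12. Naive and memory T cell genes passed 3 of 6 and cell cycle 3 of 18. Stress genes in capillary cells had a median of -0.73 in MAG4/Pt against control, and haemoglobin in B cells of -4.06 in MAG4.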

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

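The tests of explanations in this part were chosen after the results they address had been seen, while the interaction contrast was fixed beforehand. The difference between MAG4/Pt and MAG4 departed from that between Pt and control in 290 gene calls over 13 classes by the interaction test, in which each of the 3 genotypes other than control is 1 library. Of the 290 calls, 86 lay in genes called in at least 4 classes, and 27 had more than 50% of their UMIs in 1 cell. DESeq2 gave 25 calls.

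Barcodes without cells, used elsewhere only to estimate and subtract free RNA, held signals above both controls. S100a8 and S100a9 made up 0.265% of their UMIs in MAG4/Pt, against 0.148% and 0.182% in control replicates 1 and 2. Scgb1a1 made up 0.0407% in Pt and 0.0529% in MAG4/Pt, against 0.0298% and 0.00972%. Haemoglobin genes made up 0.183% in MAG4/Pt, against 0.163% and 0.00799%, and mitochondrial genes 11.6%, against 8.66% and 11.4%. Clusters left without a name also exceeded both controls. A cluster led by Il17a, Cxcr6 and Il22 held 0.749% of MAG4/Pt cells, a cluster of proliferating cells held 1.05% of them, and a cluster with few UMIs, alveolar macrophage genes and Igha held 0.852% of MAG4 cells and 0.567% of MAG4/Pt cells.

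The 21 genes lower in at least 4 classes of Pt may mark inherited variants at a few loci. Of them 11 had another of the set within 2 Mb, against a mean of 1.21 and a highest value of 9 in 10000 random sets (permutation p = 0.0001, the smallest they can give), though some neighbours belong to 1 gene family and may be regulated together, as the heat shock pair may. Of the 12 genes higher in at least 4 classes, 0 had another of their set as near. Among those 12, Slamf1 and Ifi202b lie near Ifi206 on chromosome 1 and had medians of 2.68 and 5.15 in Pt. That region thus held rises as well as falls. The median log2 fold change of the 21 lower genes against control was 0.0248 in MAG4/Pt and -4.69 in Pt. Against the control of its batch the median in Pt was -2.06, by mean CPM over classes with 1 CPM added. This measure shrinks the falls of genes nearly absent in Pt, as for Trim5, at -4.24 against -7.94 by edgeR. The 2 medians of Pt therefore cannot be set against each other. BC018473 and Gm26740 did not differ within the batch and so followed it. A general weakening of the interferon response is excluded as the whole cause, since it needs interferon-stimulated genes to fall about as far. Over 118 values of these genes in 5 classes of Pt the median was 0.24 and the first quartile -0.0653, and against control replicate 1 alone 0.33 and -0.0217. A change limited to these loci stays open.

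Cholesterol synthesis genes were higher in alveolar macrophages of both Pt and MAG4/Pt. Batch is excluded, since the lowest within-batch median was 1.01 while the controls differed by -0.13. RNA from AT2 cells is excluded as well, as it could supply 0.403% of the rise. The median for MAG4 over control replicate 2 was -0.13, and 1 library stands for each genotype.

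Plasma cells were more frequent in MAG4/Pt than in MAG4 and control replicate 2 of its batch. The ratio was 7.50 (95% interval 2.83 to 25, counting error only), and the batch split cannot give a difference between libraries of 1 batch. The definition by immunoglobulin share stays open. Counted by markers the ratio was 1.73, but control replicate 1 at 1.34% and Pt at 1.23% then lay above MAG4/Pt at 0.874%. Whether the combined genotype exceeds the sum of its parts could not be told, since the interaction of 2.15 log2 units did not pass edgeR's test (unadjusted p = 0.322).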

How the results depend on the processing

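Gene calls are given in the order Pt, MAG4 and MAG4/Pt against control, MAG4/Pt against Pt, MAG4/Pt against MAG4 and the interaction, and the reported counts were 674, 181, 244, 705, 234 and 290. Size factors, the filter on low counts, the stricter cell filter and kept doublets left every count within 1.5-fold. The genes behind a count could still change. Without the filter on low counts, 420, 109, 184, 357, 183 and 194 of the reported calls were kept. DESeq2 gave 122, 12, 17, 71, 19 and 25, thinned counts 419, 116, 138, 448, 143 and 184, and the additive model 31, 17, 22, 17 and 31 with no interaction. With a batch term it gave 278, 39, 46 and 39 in the first 4. With 1 control left out, where the fit is additive too and the contrasts share coefficients in pairs, the counts ranged from 239 to 428, 82 to 4643, 98 to 892, 82 to 4643 and 239 to 428. Naming by score gave 153 for MAG4/Pt against MAG4, and subtraction of free RNA 443 for the interaction. With classes of 10 to 19 cells added, chosen after the data had been seen, MAG4 gave 317, MAG4/Pt 681, and the contrasts of MAG4/Pt with Pt and MAG4 1060 and 533. Classes with a changed share ranged from 0 to 1 with a control left out. Plasma cells counted by markers were 1.34% and 0.507% in the controls, 1.23% in Pt, 0.506% in MAG4 and 0.874% in MAG4/Pt. With an estimated correlation 0 tests passed for each of the 17 lists, a setting in which 1 residual degree of freedom could hardly let any pass. With free RNA subtracted cell cycle passed 9 in place of 3 and haemoglobin 0 in place of 7. SREBP genes called in alveolar macrophages of Pt (10 reported) were 1 with DESeq2, 17 with a batch term and 14 to 17 with a control left out. In MAG4/Pt against control (14) they were 0 with DESeq2 and 5 when thinned. Against MAG4 (11) they were 0 with DESeq2, 17 with a batch term, 7 by score naming, 3 when thinned and 14 to 17 with a control left out. Inflammatory genes in MAG4/Pt macrophages (18) were 0 with DESeq2, 9 in the additive model and 8 to 16 with a control left out. Regulatory genes in T cells of Pt (9) were 5 with DESeq2, 0 in the additive model and 0 to 12 with a control left out, and cytotoxicity genes in T cells of MAG4/Pt against MAG4 (4) were 1, 0 and 0 to 2, and 1 by score naming. In MAG4 against control Ccl5 in fibroblasts moved from -3.32 to 0.99 with a batch term and to a range of -0.27 to 0.86 with a control left out. In MAG4/Pt against Pt, Eps8 in non-classical monocytes moved from 10.42 to -0.88 and Sfi1 in T cells from -2.13 to 0.11 with a batch term, Ccl5 in cDC2 from -4.13 to 0.42 in the additive model and 1.12 with a batch term, and Ifitm1 in B cells from -4.47 to 0.88 by score naming. Of 111 named values DESeq2 left 39 past the threshold, size factors 108 and the additive model 24. The cause of these shifts was not tested, except that a design without control replicate 2 makes MAGE-A4 and batch coincide.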

Other observations

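The test in this part was chosen after its result had been seen. Cells of the cluster led by Il17a, a cytokine of type 17 lymphocytes, numbered 12 and 15 in control replicates 1 and 2, 11 in Pt, 15 in MAG4 and 78 in MAG4/Pt. Their other leading genes included Cxcr6, Il22, Cd40lg and Icos, and the cluster was left unnamed. Proliferating cells numbered 32 and 37 in the controls, 49 in Pt, 34 in MAG4 and 109 in MAG4/Pt, and were more frequent within each batch, 1.91-fold in Pt over control replicate 1 and 2.21-fold in MAG4/Pt over MAG4 and control replicate 2. Mature dendritic cells, which carry antigen to lymph nodes, were 5.11-fold as frequent in MAG4/Pt as in those libraries (95% interval 2.57 to 11.1, counting error only). Their share did not pass edgeR's test in any contrast.

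The hypothesis that the batch split explains the cells of this cluster is excluded, since MAG4/Pt held them 3.75-fold as often as MAG4 and control replicate 2 of its own batch (95% interval 2.43 to 5.92, counting error only). In Pt over control replicate 1 the ratio was 1.15 (0.458 to 2.84). Over the 3 analysed clusters with Il17a among their leading genes the ratios were 2.53 (1.88 to 3.42) and 1.63 (0.916 to 2.94), and a further cluster led by Il17a was left out as doublets. Because MAG4/Pt is 1 library, an infection or another difference between mice could give the same result.

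A cluster led by cartilage and bone genes, with a median of 591 UMIs, made up 2.11% of control replicate 1 and 1.16% of Pt. It made up 0.01% of control replicate 2 and held 0 cells of MAG4 and MAG4/Pt, the same split between batches as that of erythroid cells. In empty droplets such genes made up 0.0601% and 0.0647% of UMIs in control replicate 1 and Pt, against 0.000412% in control replicate 2. Whether these barcodes held whole cells was not tested.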
